A study of Mus musculus with 18 samples.

How the data were processed

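Hypothalami were dissected under a microscope, frozen, and extracted with Trizol, and biotin-labelled target was made from total RNA with a whole-transcript protocol, per the labels' protocols. The deposited table holds log2 expression values, 1 per probeset and array, taken here as background corrected and normalized by the authors before deposit. That the scale is log2 was read from the values, which ran from 1.11 to 14.54 and were rounded to a few decimals. The submitters' processing notes name RMA and MAS5, with no role, order or version. Where it is used, RMA sets the arrays of a series on a common distribution, which removes most difference in total signal between arrays and compresses small differences at low intensity. The array model and the scan dates are not given in the sources used here, and scanner files were not analysed here, so background correction, detection calls and scan batches could not be examined.

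The table held 34760 probesets. The platform annotation paired 21640 of them with 1 gene symbol and 1321 with several, and it listed no gene for 11799. Only single-symbol probesets were named. Their Entrez identifiers matched the RefSeq gene table of assembly GRCm38.p6 for 21553 of 21640, which changed 0 symbols. That table served only for names and chromosome membership. Where a gene had several probesets, the brightest over all 18 arrays was used, which left 19937 genes.

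Differences were fitted on the deposited log2 values with limma (lmFit and eBayes, version 3.58.1, R 4.3.3), without covariates. The Benjamini-Hochberg adjusted p threshold was 0.05. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 30 lists, then with an estimated correlation and with fry. Single measurements were compared with two-sided exact permutation tests. In simulated arrays with the mean and spread of each real gene, 50 genes were moved by each of 4 sizes. The noise was independent between genes and the labels were correct. For the title endings, limma called 54% of the genes moved by 0.25 on the log2 scale, 96% of those moved by 0.5 and 100% of those moved by 1. For the 9 arrays whose labels agree these shares were 8%, 78% and 94%, and for the 9 whose labels contradict each other 6%, 76% and 98%. For the genotype field they were 50%, 96% and 100%. These shares do not give the sensitivity of the real comparisons, where genes vary together and the genotype labels are in doubt.

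The groups, the tests, the 30 gene lists and the rule for named genes were fixed before the data were examined. The list tests for the genotype field and for the contradicting arrays, and every fit without the array low in Xist and the array high in Ttr, were chosen after seeing the data. The rule named Wfs1 and, because no gene passed the threshold, the members of each list with the smallest p for the title endings, up to 2 per list. Predicted genes were passed over. Genes named outside this rule were chosen after their values were seen, and this is said where they appear. The labels do not say whether each array is a separate animal, so the p-values measure only the spread between arrays, part of which may be technical.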

Results

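Gene expression was measured on 18 arrays of mouse hypothalamus, from wild-type mice and mice mutant for Wfs1, on the background given as 129SV in the sample labels and 129S6 in the series text. Wfs1 encodes wolframin, a glycoprotein of the endoplasmic reticulum membrane whose loss causes Wolfram syndrome in humans. Each array carried a pair of genotype labels. One was the genotype field, repeated at the start of the sample title, and it divided the arrays into 9 KO and 9 WT. The other was the ending of the title, and it divided them into 10 ko and 8 wt. Both labels gave the same genotype on 9 arrays, 5 of them ko/KO and 4 wt/WT, where the ending is written first and the field second. They contradicted each other on the other 9 arrays, 5 labelled ko/WT and 4 labelled wt/KO. The field alternated strictly between KO and WT in the order of the samples. The ending followed the second number in the title, which was lower for every ending ko than for every ending wt. This is a reason to doubt the field more than the ending. What that number stands for is not given, so it does not settle the question. Neither label was taken as the true genotype, and the comparisons below were made by each of them. Array medians lay between 7.10 and 7.19 log2 units and the standard deviations of all values between 1.93 and 2.04. Pairs of arrays correlated at r = 0.975 to 0.991 across probesets. The same value occurred in at most 2.99% of probesets of any pair, so no array was a copy of another. The number of arrays limits the precision of every difference.

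The level of Wfs1 followed neither label. On the arrays with the ending ko it was 8.31 ± 0.31 log2 units (SD, n = 10), against 8.12 ± 0.25 (SD, n = 8) with the ending wt, a difference of 0.18 towards the arrays labelled mutant (exact permutation test, p = 0.204). By the genotype field the levels were 8.25 ± 0.35 (SD, n = 9) for KO and 8.20 ± 0.24 (SD, n = 9) for WT (exact permutation p = 0.697). Where the labels agreed, Wfs1 was 8.33 ± 0.40 (SD, n = 5) on the ko/KO arrays and 8.09 ± 0.22 (SD, n = 4) on the wt/WT arrays (exact permutation p = 0.333). Where they contradicted each other, it was 8.28 ± 0.25 (SD, n = 5) with the ending ko and 8.16 ± 0.31 (SD, n = 4) with the ending wt (exact permutation p = 0.492). The Benjamini-Hochberg adjusted values of the 4 tests ran from 0.656 to 0.697. The mean was higher on the arrays labelled mutant by the ending in the whole series and in both sets of 9, and by the field in the whole series, the opposite of what loss of the transcript gives. On the contradicting arrays those labelled mutant by the field are the ones with the ending wt, and there the mean was lower. The genotype labels are therefore in doubt and every difference below is one between arrays labelled in that way. Leaving out the array labelled ko/KO 1 turned the field difference to -0.0029. Leaving out wt/KO 3 raised the difference by ending to 0.25, and leaving out ko/KO 5 raised that on the agreeing arrays to 0.36, each with an unadjusted limma p of 0.043. On the contradicting arrays the difference of 0.12 became 0.28 without wt/KO 3 and 0.045 without wt/KO 2. Which part of the gene the probeset reads is not given, and a probeset outside the altered part would not register the mutation. The values did not form a single group, however, with 10 arrays from 7.86 to 8.07 and 8 from 8.36 to 8.72. The closing part gives a match of these levels to the titles in another order. That match argues against correct labels with a probeset that the mutation leaves unchanged.

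**Figure D1:**
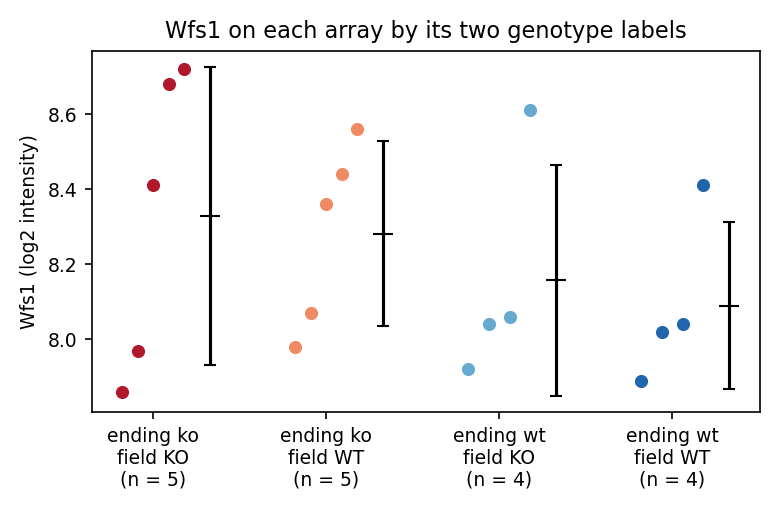
Wfs1 level in log2 intensity units on each of the 18 arrays (points), grouped by title ending and genotype field, with the mean and SD of each group (dash and bars). Every group holds arrays from 7.86 to 8.07 and arrays from 8.36 to 8.72, and none lies between.

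By title ending, the arrays labelled ko were compared with those labelled wt over the whole series. As a group, 18 of 18 measured oligodendrocyte and myelin genes had a higher mean with the ending ko, with a median log2 difference of 0.070 (camera adjusted p = 0.0030, and adjusted p = 0.803 with an estimated correlation). Among them were Gpr37, a receptor of myelinating cells, at 0.16 (SE 0.082, n = 10 and 8) and Fa2h, which hydroxylates myelin lipids, at 0.11 (SE 0.067). Thalamic markers were shifted up, with 12 of 15 higher and a median of 0.098 (adjusted p = 0.0030, and 0.803 as the adjusted p with an estimated correlation), among them Zmat4 at 0.12 and Synpo2 at 0.15. Of the circadian clock genes 15 of 16 were higher, with a median of 0.048 (adjusted p = 0.012, and adjusted p = 0.803 with an estimated correlation). The nuclear receptor Rorb differed by 0.17 (SE 0.077) and Dbp, a clock-driven transcription factor, by 0.12 (SE 0.056). Respiratory chain subunits were higher for 20 of 24, with a median of 0.040 (adjusted p = 0.026, and adjusted p = 0.803 with an estimated correlation), including the complex III core proteins Uqcrc1 at 0.078 and Uqcrc2 at 0.071.

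A pair of lists was shifted down with the ending ko. Of the hypothalamic regional markers, mostly developmental transcription factors, 19 of 24 were lower, with a median of -0.054 (camera adjusted p = 0.013, and adjusted p = 0.803 with an estimated correlation). Lmx1b differed by -0.18 (SE 0.065) and Hmx2 by -0.15 (SE 0.065). Of the choroid plexus markers 12 of 14 were lower, with a median of -0.10 (adjusted p = 0.019, and adjusted p = 0.803 with an estimated correlation), and the potassium channel subunit Kcne2 differed by -0.25 (SE 0.098) and the tight junction protein Cldn2 by -0.099. Cldn2 was at most 5.63 on any array, below the lower quartile of all values on every array (5.81 at the lowest). The choroid plexus shift rested on the array labelled wt/WT 3, where Ttr was 12.8, since its adjusted p was 0.548 without that array and 0.051 without wt/WT 1. The shift of the hypothalamic regional markers missed the threshold without wt/KO 1 (adjusted p = 0.092) or without ko/WT 4, where Xist was 5.93 (adjusted p = 0.095).

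G-protein signalling, the subject of the study's title, was followed with 4 lists. Of the regulators of G-protein signalling, which speed up GTP hydrolysis by G protein alpha subunits, 13 of 21 measured genes were higher and 8 lower, with a median log2 difference of 0.034 (camera adjusted p = 0.539). The members with the smallest p were Rgs14 at -0.15 (SE 0.059, adjusted p = 0.884) and Rgs13 at -0.20 (SE 0.084, adjusted p = 0.884). Rgs13 was at most 4.57 on any array, below the lower quartile of all values on every array (5.81 at the lowest). Of the heterotrimeric G protein subunits 14 were higher and 15 lower, and the list's median of -0.0020 and its mean of 0.012 differed in sign (adjusted p = 0.636). Gng3 differed by 0.12 (SE 0.044) and Gng5 by 0.14 (SE 0.076), both G protein gamma subunits, and without wt/WT 1 the latter was 0.073. Enzymes and effectors of cyclic AMP were higher for 21 of 27 (median 0.035, adjusted p = 0.087), with the phosphodiesterases Pde7b at 0.087 and Pde1b at 0.064. Neuropeptide and monoamine receptors were higher for 21 of 36 (adjusted p = 0.841), with the delta opioid receptor gene Oprd1 at -0.11 and the neurotensin receptor gene Ntsr1 at 0.11.

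Genes of endoplasmic reticulum stress did not pass the threshold by title ending. Of 31 genes of the unfolded protein response 14 were higher and 17 lower (camera adjusted p = 0.881), with the stress sensor Atf6 at 0.11 (SE 0.049) and Atf3 at -0.10. Of the WFS1-associated proteins 8 of 12 were higher (adjusted p = 0.588), and the calcium channel Itpr3 differed by -0.077. Of 28 hypothalamic neuropeptides 20 were lower (adjusted p = 0.408), with Qrfp at -0.16 (SE 0.053) and Cck at 0.15 (SE 0.064). The adjusted p was 0.500 for growth hormone and insulin signalling, where Stat5a differed by -0.12 and Socs2 by 0.15, and 0.317 for pituitary markers, where Gh differed by -0.22 and Ghrhr by -0.14. It was 0.805 for calcium handling (Cacna1h -0.070, Calb1 -0.10), 0.408 for immediate early genes (Npas4 0.21, Jun 0.11) and 0.408 for glucocorticoid response genes (Mt1 0.089, Errfi1 0.071). Genes of monoamine, GABA and other transmitter synthesis and transport had an adjusted p of 0.286. Among them were the vesicular transporter genes Slc17a6 at 0.10 and Slc18a1 at -0.14.

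Markers of other cells and regions were not shifted past the threshold by title ending. Of the astrocyte markers 13 of 15 were higher (camera adjusted p = 0.075), with Gjb6 at 0.13 and Slc4a4 at 0.091, and of the microglia markers 9 of 14 (adjusted p = 0.286), with Csf1r at 0.088 and C1qc at 0.11. The adjusted p was 0.500 for endothelial and mural markers (Slco1a4 0.14, Tek 0.088), 0.706 for ependymal and tanycyte markers (Col23a1 -0.14, Foxj1 -0.088) and 0.825 for meningeal and fibroblast markers (Dcn 0.26, Slc6a13 0.16). It was 0.825 for cortical and hippocampal markers (Tbr1 0.16, Lamp5 0.12), 0.805 for striatal markers (Scn4b 0.19, Gpr6 -0.11) and 0.338 for pan-neuronal markers (Nefm 0.15, Nefh 0.11). Blood markers (S100a9 -0.12, Alas2 -0.17), ribosomal proteins (Rpl27 -0.092, Rpl4 0.051) and sex-linked genes (Xist -0.43, Uty 0.063) had adjusted p values of 0.460, 0.893 and 0.825. Alas2 turned to 0.077 without wt/KO 2, Xist to 0.030 without ko/WT 4 and Rpl27 to 0.0067 with the mean of its probesets. Without wt/KO 1 Uty was 0.0044 and S100a9 -0.20, and leaving out any 1 of wt/KO 3, wt/KO 4, ko/KO 2 and ko/KO 3 gave Uty values from 0.024 to 0.097. The level of Uty was at most 4.90 on any array, below the lower quartile of all values on every array (5.81 at the lowest). S100a9 was -0.073 without wt/WT 2, and Rpl4 0.031 without wt/WT 1 and 0.029 without ko/KO 5. Median and mean differed in sign for meningeal, cortical and ribosomal genes.

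No single gene passed the threshold by title ending. Of 19937 genes limma called 0, its lowest adjusted p was 0.884, and 923 genes had an unadjusted p under 0.05 where 997 would by chance, 373 of them higher and 550 lower. Adjusted over the list alone, 0 members of the 30 lists passed. Of the 6 list calls, 0 held with an estimated correlation and 0 with fry (lowest adjusted p = 0.768). The median standard error was 0.062 log2 units. Leaving out 1 array moved 16 of the 59 named genes other than Wfs1 by more than 1.5 times. Beyond those given above, Kcne2 was -0.16 without wt/WT 3, Slc6a13 0.098 and Gpr6 -0.054 without wt/WT 2, Socs2 0.094 without wt/WT 1, Fa2h 0.068 and Jun 0.071 without ko/KO 1, and C1qc 0.073 without ko/KO 4. Atf3 was -0.048 without wt/KO 3, Calb1 -0.053 without wt/KO 1 and Mt1 0.056 without ko/WT 3. Circadian clock genes had an adjusted p of 0.105 after quantile normalization and 0.107 without the dimmest 40% of genes. The choroid plexus values there were 0.105 and 0.403, and those of the respiratory chain 0.318 and 0.403. The respiratory chain list also missed the threshold without any 1 of wt/WT 1, wt/WT 2, ko/KO 2, ko/KO 4, ko/WT 1, ko/WT 3, ko/WT 5 and wt/KO 2, with adjusted p values from 0.067 to 0.162.

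Where both labels gave the same genotype, the choroid plexus and clock lists passed the threshold. These arrays are part of those compared by title ending, so this is no second finding. On the separate, contradicting arrays neither list passed, in tests added after seeing the data. Clock genes were higher there with the ending ko for 10 of 16 (median 0.00825, camera adjusted p = 0.981). Choroid plexus markers were higher for 8 of 14 (median 0.038, camera adjusted p = 0.208). All 14 measured choroid plexus markers were lower on the 5 ko/KO arrays than on the 4 wt/WT arrays, with a median log2 difference of -0.20 (camera adjusted p = 0.0023, and adjusted p = 0.809 with an estimated correlation). Kcne2 differed by -0.37 (SE 0.15) and Cldn2 by -0.19 (SE 0.079). Without the array labelled wt/WT 3 the list's adjusted p was 0.081, and it was 0.240 without the dimmest 40% of genes. Circadian clock genes were higher for 15 of 16, with a median of 0.089 (adjusted p = 0.0076, and adjusted p = 0.809 with an estimated correlation), among them Rorb at 0.24 (SE 0.12) and Dbp at 0.23 (SE 0.081). Their adjusted p was 0.108 after quantile normalization and 0.252 without the dimmest 40% of genes.

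The G-protein lists did not pass the threshold on these arrays. Of the regulators of G-protein signalling 15 of 21 were higher (median 0.033, camera adjusted p = 0.172), of the G protein subunits 19 of 29 (median 0.064, adjusted p = 0.193) and of the cyclic AMP enzymes and effectors 19 of 27 (median 0.066, adjusted p = 0.053). Unfolded protein response genes were higher for 21 of 31 (adjusted p = 0.146). Oligodendrocyte, astrocyte and microglia markers each had an adjusted p of 0.053, with 17 of 18, 12 of 15 and 11 of 14 genes higher. The activity-dependent transcription factor Npas4 differed by 0.39 (SE 0.12), and growth hormone (Gh), a pituitary product, by -0.44 (SE 0.13). Adjusted over the list alone, 4 members passed, namely Gh and Ghrhr among the pituitary markers, S100a9 among the blood markers and the neuropeptide Y receptor gene Npy2r at 0.38 (SE 0.096), the last chosen after its value was seen. Over all genes limma called 0, with a lowest adjusted p of 0.384. An unadjusted p under 0.05 occurred for 2218 genes where 997 would by chance, 579 higher and 1639 lower. With fry 0 lists passed (lowest adjusted p = 0.406). The 2 lists past the camera threshold became 4 without ko/KO 1 or ko/KO 2, 5 without wt/WT 3 or ko/KO 5, and 7 without wt/WT 4.

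Where the labels contradicted each other, most regional markers of the hypothalamus were lower with the ending ko, and most markers of the thalamus, its neighbour, were higher. Neither shift passed the threshold with an estimated correlation. Of the hypothalamic regional markers 22 of 24 were lower, with a median log2 difference of -0.078 between 5 and 4 arrays (camera adjusted p = 4.2e-08, and adjusted p = 0.451 with an estimated correlation). Thalamic markers were higher for 13 of 15, with a median of 0.15 (adjusted p = 5.3e-05, and adjusted p = 0.661 with an estimated correlation), among them Synpo2 at 0.23 and Zmat4 at 0.14. Hypothalamic neuropeptides were lower for 21 of 28 (median -0.11, adjusted p = 9.2e-05), unfolded protein response genes for 22 of 31 (median -0.042, adjusted p = 0.0015) and receptors for 26 of 36 (median -0.032, adjusted p = 0.019), with adjusted p values of 0.661, 0.661 and 0.757 with an estimated correlation. Oligodendrocyte genes were higher for 16 of 18 (median 0.074, adjusted p = 0.013, and adjusted p = 0.757 with an estimated correlation). Regulators of G-protein signalling were higher for 9 and lower for 12 (adjusted p = 0.393), and G protein subunits higher for 11 and lower for 18 (adjusted p = 0.289).

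These list tests were added after seeing the data. The contradicting arrays are also part of those compared by title ending. The thalamic, hypothalamic regional and oligodendrocyte shifts are therefore no second finding. Without ko/WT 4 the neuropeptide list had an adjusted p of 0.078, the receptor list 0.140 and the oligodendrocyte list 0.175, and without wt/KO 1 the unfolded protein response list had 0.072. The receptor list also missed the threshold without wt/KO 1, wt/KO 3, ko/WT 2 or ko/WT 5 (adjusted p from 0.069 to 0.199), and the oligodendrocyte list without wt/KO 1, wt/KO 2 or ko/WT 5 (adjusted p from 0.101 to 0.20). Of single genes limma called 0, with a lowest adjusted p of 0.9998. An unadjusted p under 0.05 occurred for 546 genes where 997 would by chance, 348 higher and 198 lower. Adjusted over the list alone, 1 list member passed, the choroid plexus transport protein Ttr at 0.86 (SE 0.19), chosen after its value was seen. With fry 0 lists passed (lowest adjusted p = 0.702).

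The differences in these separate sets of 9 arrays did not run in parallel. Across 19937 genes, which are not independent replicates, the log2 differences between the endings ko and wt correlated at r = -0.145 and rho = -0.146. Of 2218 genes with an unadjusted p under 0.05 where the labels agreed, 856 (38.6%) had the same sign where they contradicted each other. An unadjusted p under 0.05 occurred in both sets for 59 genes, where 60.7 would by chance, and 13 of these had the same sign. Hypothalamic neuropeptides had a median of 0.054 in the agreeing set and -0.11 in the contradicting set, and thalamic markers 0.0025 and 0.15. Oligodendrocyte genes were higher with the ending ko in both, at 0.084 and 0.074. The correlation ranged from -0.409 without wt/KO 4 to 0.098 without wt/KO 1, and it was -0.018 without ko/WT 2 and -0.287 without ko/WT 5. A test of whether the difference between endings itself differed between field KO and field WT called 0 genes with limma (lowest adjusted p = 0.927, 1033 genes at an unadjusted p under 0.05). It set ko/KO minus wt/KO against ko/WT minus wt/WT, so it does not test whether the agreeing and contradicting sets differ.

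**Figure D2:**
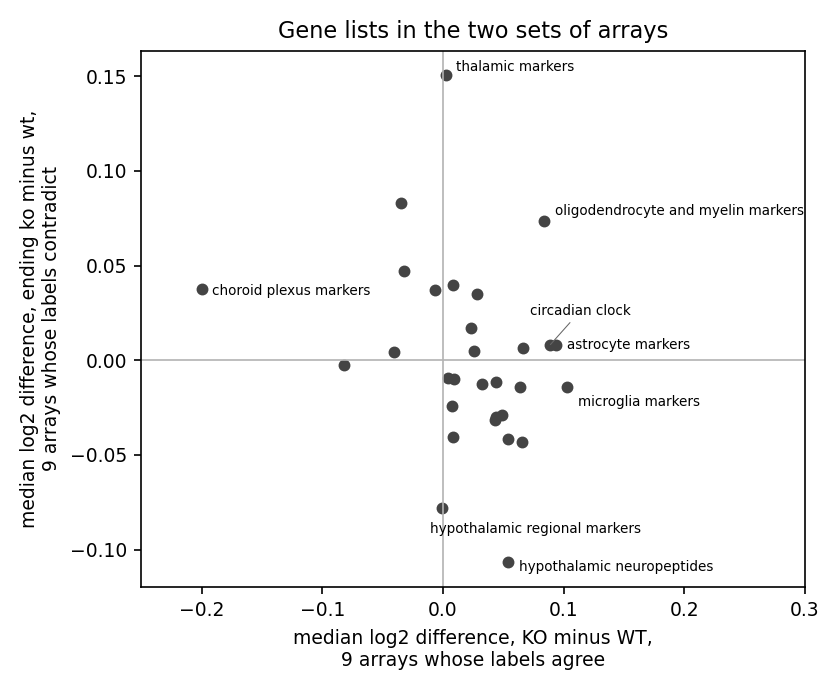
Median log2 difference of each of the 30 gene lists (points) on the 9 arrays whose labels agree (x axis) and the 9 whose labels contradict each other (y axis), ending ko minus ending wt on both axes. Choroid plexus markers lie at -0.20 and 0.038, and thalamic markers at 0.0025 and 0.15.

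By genotype field, the arrays labelled KO were compared with those labelled WT, again over the whole series. The agreeing and the contradicting arrays are all part of this comparison, the latter with the sign turned, since field KO there has the ending wt. A list shift seen in either set and again here is therefore no second finding. Hypothalamic regional markers were higher for 15 of 24 (median 0.076, camera adjusted p = 0.0042), hypothalamic neuropeptides for 21 of 28 (median 0.059, adjusted p = 0.0042) and unfolded protein response genes for 26 of 31 (median 0.036, adjusted p = 0.0042), each with an adjusted p of 0.446 with an estimated correlation. On the agreeing arrays 12 of the regional markers were higher and 12 lower (median -5e-04, adjusted p = 0.827). Thalamic markers were lower by field for 12 of 15 (median -0.068, adjusted p = 0.256). Receptors, microglia markers and clock genes were higher for 22 of 36, 12 of 14 and 14 of 16 (adjusted p = 0.013 each, and adjusted p = 0.446 each with an estimated correlation). Choroid plexus markers were lower for 13 of 14 (median -0.10, adjusted p = 0.0042, and adjusted p = 0.446 with an estimated correlation). With fry 0 lists passed (lowest adjusted p = 0.511). Regulators of G-protein signalling were higher for 16 of 21 (adjusted p = 0.097) and G protein subunits for 19 of 29 (adjusted p = 0.063). Dcn, a proteoglycan of fibroblasts, differed by 0.32 (SE 0.15), Npas4 by 0.20 (SE 0.090) and Gh by -0.20 (SE 0.10).

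These list tests too were added after seeing the data. The 7 lists past the threshold became 3 without ko/WT 4, 4 without ko/WT 5, and 11 without ko/KO 2 or ko/KO 3. Without ko/WT 4 the adjusted p was 0.051 for the regional markers, 0.083 for the neuropeptides, and 0.056 for both receptors and microglia markers. Without ko/WT 5 it was 0.069 for the regional markers, 0.056 for the receptors and 0.058 for the microglia markers. The microglia list had 0.122 without ko/KO 4, and the receptor list 0.061 without the arrays low in Xist and high in Ttr. The choroid plexus, clock and unfolded protein response lists stayed past the camera threshold in all 18 fits that left out 1 array. Their highest adjusted p values were 0.031 (without wt/WT 3), 0.049 (without ko/KO 5) and 0.025 (without ko/KO 4). Of single genes limma called 0, with a lowest adjusted p of 0.694. An unadjusted p under 0.05 occurred for 1386 genes where 997 would by chance, 496 higher and 890 lower. Adjusted over the list alone, 4 members passed, each chosen after its value was seen: the neuropeptide gene Adcyap1 at 0.22 (SE 0.057), Rxrg at 0.21 (SE 0.056), Fezf1 at 0.22 (SE 0.062) and the Y-linked gene Kdm5d at -0.24 (SE 0.077). Kdm5d ran from 4.81 to 5.63, below the lower quartile of all values on every array (5.81 at the lowest), so its difference may be one of background. Its list held 4 measured genes.

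Some genes varied widely between single arrays, and these were chosen after their values were seen. Xist, the transcript that silences an X chromosome in females, was 5.93 on the array labelled ko/WT 4 and at least 10.31 on the other 17. Ttr, the thyroid hormone carrier made by the choroid plexus, ran from 8.01 to 12.8, the latter on the array labelled wt/WT 3. Its difference was the lowest of 19937 genes on the agreeing arrays, at -1.66 (SE 0.62, limma adjusted p = 0.400), and by genotype field, at -1.18 (SE 0.40, limma adjusted p = 0.694), and without that array it was -0.87 and -0.80. By title ending it was -0.40 (SE 0.47, limma adjusted p = 0.896), and 0.081 without that array. The dopamine transporter gene Slc6a3 ran from 9.06 to 10.75 and tyrosine hydroxylase (Th) from 8.93 to 10.16, both highest on wt/KO 4 and lowest on ko/KO 2. Tph2, which makes serotonin in the brainstem raphe, ran from 5.61 to 8.06, and vasopressin (Avp) from 9.44 to 10.89. The array labelled ko/WT 4 was highest for Tph2 and lowest for Avp and oxytocin (Oxt).

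**Figure D3:**
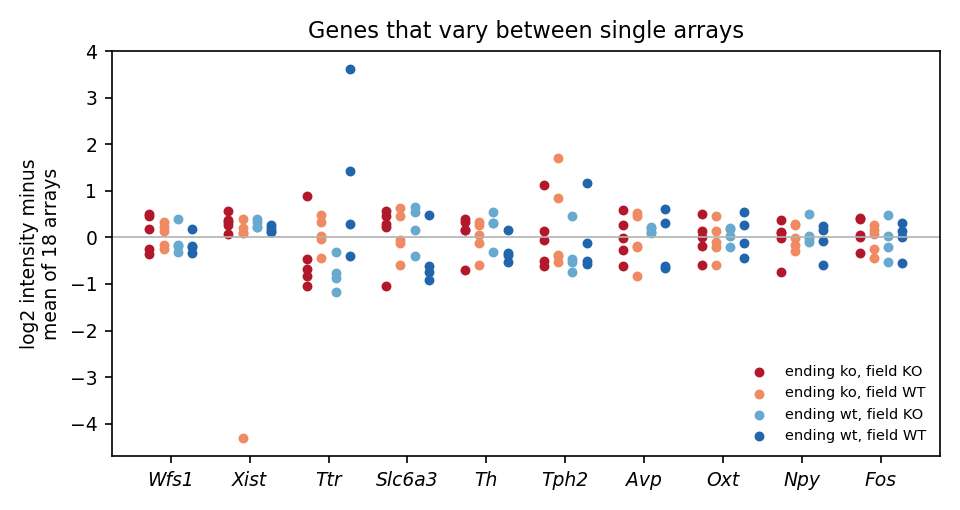
Log2 intensity of 10 genes on each of the 18 arrays (points), minus the mean of all arrays, coloured by title ending and genotype field. Xist on the array labelled ko/WT 4, at 5.93, and Ttr on that labelled wt/WT 3, at 12.8, stand far from the rest.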

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

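The tests of a single X chromosome, of 2 active X chromosomes and of a failed array were set before their results were seen, and the other tests in this part were chosen only afterwards.

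On single arrays, 8 values among named genes and array measures stood apart from their own labelled group, in 244 groups of 4 or 5 arrays where chance gives about 12.2, so the number of such values is not itself unusual. Stat5a was 7.77 on wt/KO 4, where the other 3 arrays of its group lay at 7.70 to 7.71. Foxj1 was 7.40 on wt/WT 4, against 7.59 to 7.60. Kcne2 was 6.47 on ko/KO 2, against at most 6.06. Lamp5 was 8.26 on ko/KO 1, against at most 7.91, and 8.29 on ko/WT 3, against at most 7.93. Hmx2 was 8.22 on wt/KO 4, against at most 7.79. The standard deviation of all log2 values was 1.95 on ko/KO 2, against at least 2.01. Xist was 5.93 on ko/WT 4, against at least 10.33.

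Xist on the array labelled ko/WT 4, against 10.48 ± 0.13 (SD) on the other 17, lay close to that array's lower quartile of 5.91, and since its background is not known the measured 23.5-fold difference is read only as a lower bound. A male animal is argued against, since 0 of the 3 Y-linked genes Kdm5d, Uty and Eif2s3y exceeded the other arrays. A failed array is argued against by its median correlation with the others of r = 0.9863, within their range of 0.9793 to 0.9884, and 2 active X chromosomes by a median log2 difference of 0.005294 over 288 X-linked genes, against 0.022 over 8135 autosomal genes. A single X chromosome remains a candidate explanation, since the genes that escape X inactivation, Kdm6a, Kdm5c, Eif2s3x and Ddx3x, were each lower than on any other array, with a median z score of -2.625. No biological explanation from the design was tested, since the labels give no sex.

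The high Ttr of the array labelled wt/WT 3, 12.8 against 8.98 ± 0.72 (SD, n = 17), was 14.2-fold above the mean of the others. A failed array is argued against by a median correlation of r = 0.9849, within the range of the others. Choroid plexus tissue in the dissected piece may account for it: 8 of the 13 other choroid plexus markers were highest on this array, where 0.722 would by chance, led by Kcnj13 at 1.02 and Kcne2 at 0.87 log2 units above the others. The count of 8 lies between the 10 set as a sign of tissue and the 4 set as a sign against it. Both limits were set after the data were seen. Whatever its size, such a count cannot tell added tissue from a change in these genes themselves. No biological explanation from the design was tested, since the array's genotype labels are in doubt.

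With 0 genes called in each of the 4 comparisons, 100 of 100 splits of the same arrays, the real one included, called at least as many, as any split must, so these counts say nothing about chance. Any gene was called by 1 of the other splits for the title ending, 4 for the genotype field, 7 for the agreeing arrays and 6 for the contradicting arrays, and the highest counts were 1, 26, 62 and 7 genes.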

How the results depend on the processing

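The alternative with the arrays low in Xist and high in Ttr left out was chosen after seeing the data. Calls stayed at 0 in each of the 12, 12, 11 and 11 alternatives run for the title ending, the genotype field, the agreeing and the contradicting arrays, and in the 18, 18, 9 and 9 fits that leave out 1 array, with lowest adjusted p values of 0.225, 0.120, 0.111 and 0.350. The Wfs1 difference ran, with 1 array left out, from 0.14 to 0.25 by title ending, from -0.0029 to 0.10 by genotype field, where it reversed without ko/KO 1, from 0.14 to 0.36 on the agreeing arrays and from 0.045 to 0.28 on the contradicting arrays. Its limma p was 0.043 by title ending without wt/KO 3 and on the agreeing arrays without ko/KO 5, and in the other alternatives it stayed above 0.05. The 6 list calls by title ending became 0 with an estimated correlation, 0 with fry and 3 with quantile normalization. The 2 of the agreeing arrays became 0 with an estimated correlation, 0 with fry, 1 with quantile normalization, 0 without the dimmest 40% of genes and 5 without the doubted arrays, and ran from 2 to 7 with 1 array left out. The list calls added later ran with 1 array left out from 3 to 11 by genotype field and from 5 to 8 on the contradicting arrays. The correlation between the sets of 9 arrays ran from -0.41 to 0.098 with 1 array left out. Among 757 alternative values of the other 59 named genes, 0 passed the threshold and 4 reversed: Rpl27 to 0.0067 with the mean of its probesets, Xist to 0.013 without the doubted arrays, and with 1 array left out Alas2 (-0.25 to 0.077) and Xist (-0.51 to 0.030), whose low array sets its difference. Apart from Xist, the cause was not tested. The pseudocount was not run because the values are already on a log scale, and signal over background could not be examined. No paired analysis was possible because the titles carry no replicate number shared between groups.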

Other observations

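All tests in this part were chosen only after the values were seen. Of 8 pairs of neuronal and myelin genes, 6 varied together across the 18 arrays, among them the dopamine genes and a pair of peptide genes. The dopamine transporter gene Slc6a3 followed the vesicular monoamine transporter gene Slc18a2 (r = 0.978, rho = 0.976), tyrosine hydroxylase (r = 0.947, rho = 0.861) and the decarboxylase gene Ddc (r = 0.935, rho = 0.875). Each of these 6 permutation p values was 1e-05, the smallest that the permutations can give, and the Benjamini-Hochberg values over 8 relations were 1.6e-05 for r and 2.0e-05 for rho. Vasopressin followed oxytocin (r = 0.890, rho = 0.858, each with the same p and adjusted values). Without the 2 arrays farthest from the median these 4 values of r were 0.968, 0.919, 0.904 and 0.905. On arrays with a first title number up to 10 (n = 10) they were 0.984, 0.910, 0.886 and 0.977, and on the others (n = 8) 0.969, 0.956, 0.954 and 0.693. Here and below this split takes the titles as given, and whether they match the value columns is in doubt.

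The serotonin genes Tph2 and Slc6a4 correlated at r = 0.889 (permutation p = 1e-05, adjusted 1.6e-05) and rho = 0.705 (permutation p = 0.0016, adjusted 0.0021). The r was 0.756 without the 2 farthest arrays, 0.900 on arrays with a first title number up to 10 and 0.395 on the others. On the others Tph2 ran only from 5.61 to 6.24, near the lower quartile of all values, against 5.79 to 8.06 on the former. So narrow a range cannot show whether the relation is weaker there. The myelin genes Mbp and Mog correlated at r = 0.733 (permutation p = 3.1e-04, adjusted 4.1e-04) and rho = 0.787 (permutation p = 1.9e-04, adjusted 3.0e-04), with r = 0.644 without the 2 farthest arrays and 0.731 and 0.789 on the same sets of arrays. Peptides of neighbouring neuron populations showed no relation past the threshold: Npy and Pomc had r = -0.076 (permutation p = 0.766, adjusted 0.767) and rho = -0.173 (permutation p = 0.493, adjusted 0.563), and Hcrt and Pmch had r = 0.076 (permutation p = 0.767, adjusted 0.767) and rho = -0.0073 (permutation p = 0.977, adjusted 0.977). For Npy and Pomc r was -0.099 without the 2 farthest arrays, 0.0025 on arrays with a first title number up to 10 (n = 10) and -0.276 on the others (n = 8). For Hcrt and Pmch these values were 0.141, 0.145 and -0.607. After removing the first principal component of all genes r was -0.102 for the former pair and 0.320 for the latter, and from 0.757 to 0.965 for the other 6 pairs.

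Wfs1 itself fell into separate clusters that cross every label, with 10 arrays from 7.86 to 8.07 and 8 from 8.36 to 8.72, a gap of 0.29 where the next widest was 0.12. A candidate explanation, found by looking at these Wfs1 values under 3 arrangements of the labels, is that the titles and the value columns run in different orders: with the title endings laid over the columns in the order of the first title number, the lower cluster matched the ending ko and the upper the ending wt on 18 of 18 arrays (exact permutation p = 2.2853e-05, the smallest possible, or 6.9e-05 after multiplying by the 3 arrangements). The order comes from the titles and not from the values, so this match argues against correct labels with a Wfs1 level that the mutation leaves unchanged, though the order was picked after Wfs1 was seen and the match is no independent test of the candidate explanation, which stays open. The samples are listed with first number 10 first and 1 between 19 and 20, so the listed order is not numeric. With Wfs1 left out, limma called 1 gene in the order of the first title number, the complement gene C4b, chosen after its value was seen. C4b was 8.36 to 8.61 on 10 arrays and 7.64 to 8.19 on 8 (exact permutation p = 2.3e-05, limma adjusted p = 2.1e-05 with Wfs1 kept in). Of 100 splits, that order included, 3 called as many (highest other 2). C4b had no part in picking the order. Since that order divides the arrays just as the Wfs1 clusters do, C4b shows only that another gene varied with Wfs1. In an earlier draw of 60 splits with Wfs1 kept in, 59 called no gene and 1 called 2987, against 2 for that order; no array was reassigned and no other comparison is reported on this basis.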
